A study of Mus musculus with 18 samples.

How the data were processed

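The samples were IMCD3 cells, a mouse line from the inner medullary collecting duct of the kidney. Per the labels, wild-type cells, a line without Ift140 and a line without Dync2h1 were kept static or exposed to fluid flow of 0.7 dyne/cm2 for 3 h in microslide chambers. Each of the 6 groups holds 3 libraries of total RNA, 18 in all. The labels give passage 10 to 15 for the cells and do not say whether replicates were separate cultures or how many clones stand for each knockout. The p-values therefore measure the spread between these samples only.

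Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned with Bowtie2 2.1.0 and quantified with RSEM 1.2.31, with builds mm10 and GRCm38.p5 named. Aligner settings and the gene annotation release were not stated. The deposited values of the authors are TPM, transcript shares scaled by gene length to a fixed total, 1 file per library and 49845 gene names per file. The unit was read from the values: the gene rows of every library sum to the same total, as TPM does, and the leading row that repeats this sum was left out. TPM keeps no sequencing depth, so the precision that depth gives is not known for any library. A value of 0 can be no reads or a failed estimate for a gene that shares its sequence, and no fold is given against a group listed at 0.

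Gene names were matched to GENCODE vM21 on GRCm38 for coordinates and gene types. Of the names, 47220 matched as given and 447 through an older symbol, such as Ctgf for Ccn2 and Cyr61 for Ccn1. A further 2176 were not matched and stayed in the tests without coordinates, and 26 names had been turned into calendar dates.

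The plan, written before the data were examined, was a count-based test. TPM are not counts, so limma (version 3.58.1 in R 4.3.3) on log2 values took its place. Libraries were scaled with a trimmed mean of log ratios, with 30% of the ratios and 5% of the abundances trimmed and no weights. Genes with at least 1 TPM in at least 3 libraries were kept, 16718 in all. The fit used log2(scaled TPM + 1), 6 group means, all 18 libraries and 12 residual degrees of freedom, with empirical Bayes moderation and a mean-variance trend. A gene passed when its Benjamini-Hochberg adjusted p was under 0.05, with no minimum fold. An exact rank test of 3 against 3 libraries cannot go below p = 0.1, so every smaller p-value rests on the model.

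The comparisons were flow against static in each genotype, the difference of that response between each knockout and wild type, the mean of both differences, and each knockout against wild type in static and in flow culture. The 34 gene lists, written down before the data were examined, named 711 members, of which 576 were measured. Lists were tested with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Adjusted p-values of lists are over the 34 lists of a comparison. Members that passed were counted over all genes and with p-values adjusted over the list alone.

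Genes were named by a rule fixed with the plan. It takes the 10 largest rises and the 10 largest falls of each flow and static comparison among genes that passed, with a mean of at least 5 TPM and no overlap between the groups. It adds up to 4 members of each list that passed, by smallest p, and for the differences between responses the 6 largest in each direction. Names of predicted genes were skipped. The static comparisons share their wild-type libraries, so their overlap was set against simulated groups without change drawn around the same libraries.

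The method was tested on simulated data with known changes. Values were drawn for each gene independently, from a normal distribution with its mean and modelled spread. These draws hold no deviating library and no correlation between genes. In the flow comparison of wild-type cells, 50.7% of the genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were found again. For the difference between the Ift140 knockout and wild-type responses the shares were 22.4%, 56.7% and 93.9%, and for Dync2h1 14.9%, 58.2% and 87.9%. Of the genes that passed, 14 of 176 had not been changed in the wild-type flow comparison, more than the threshold of 0.05 allows on average, against 7 of 122 and 4 of 111 in these differences. In 20 draws without change no list passed for flow in wild type or for the Ift140 difference, and lists of the other comparisons were not drawn. Since genes were drawn independently, these draws cannot show how often lists of correlated genes pass without change.

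Alternatives changed the scaling, the filter, the pseudocount, the threshold, the libraries in the fit, the list test and the use of replicate numbers. Those chosen after the data had been seen were quantile normalisation, pseudocounts of 0.1 and 5, no mean-variance trend, weights per library, protein-coding genes only, the fit without the library labelled Ift140 knockout flow replicate 3 and the fit without 4 chromosomes.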

Results

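The data are RNA sequencing values of IMCD3 cells, which carry primary cilia, the single sensory projections of kidney tubule cells. Ift140 and Dync2h1 encode parts of the transport machinery that builds and maintains the cilium. The comparisons ask what 3 h of fluid flow changes in these cells, which of those changes differ when either gene is knocked out, and how the knockout lines differ from wild type. There are 6 groups of 3 libraries. Values are scaled TPM, given as mean ± SD with n = 3 per group, and TPM keeps no depth. Fold changes are log2 differences of TPM + 1 with their SE from limma, so that folds of genes near 0 TPM come out small, and p-values are adjusted by Benjamini-Hochberg.

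Ift140 (GRCm38, chromosome 17, 25016085 to 25099495) was read in each library as a check of the labels. It stood at 16.5, 19.5 and 18.8 TPM in the static wild-type libraries and at 6.26, 6.44 and 7.45 in the static Ift140 knockout libraries, a change of -1.32 (SE 0.20) with adjusted p = 0.00025. Under flow the wild-type libraries held 16.5, 15.1 and 18.5 TPM and the Ift140 knockout libraries 7.65, 8.53 and 15.4, a change of -0.67 (SE 0.20) with adjusted p = 0.0295. The library labelled Ift140 knockout flow replicate 3 thus lay near the wild-type level for this gene, and directions drawn from the Ift140 knockout flow group include it. Dync2h1, which is not targeted in this line, was also higher in that library, at 42.32 TPM against 22.85 and 28.52 in replicates 1 and 2. The raised Ift140 value alone therefore does not show a wrong label. That call under flow was lost with the deposited scaling (adjusted p = 0.0801) and with only the groups compared in the fit (adjusted p = 0.205).

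Dync2h1 (GRCm38, chromosome 9, 6928503 to 7184446) stood at 40.4, 45.4 and 33.7 TPM in static wild-type cells and at 15.1, 9.55 and 15.4 in the static Dync2h1 knockout, a change of -1.53 (SE 0.21) with adjusted p = 5.64e-05. Under flow it changed by -1.69 (SE 0.21) with adjusted p = 2.12e-05. Each targeted gene kept RNA in its own knockout, which a knockout that acts on the protein leaves possible. Neither gene passed for flow in wild-type cells (Ift140 -0.12, adjusted p = 0.733, and Dync2h1 -0.32, adjusted p = 0.321).

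**Figure D1:**
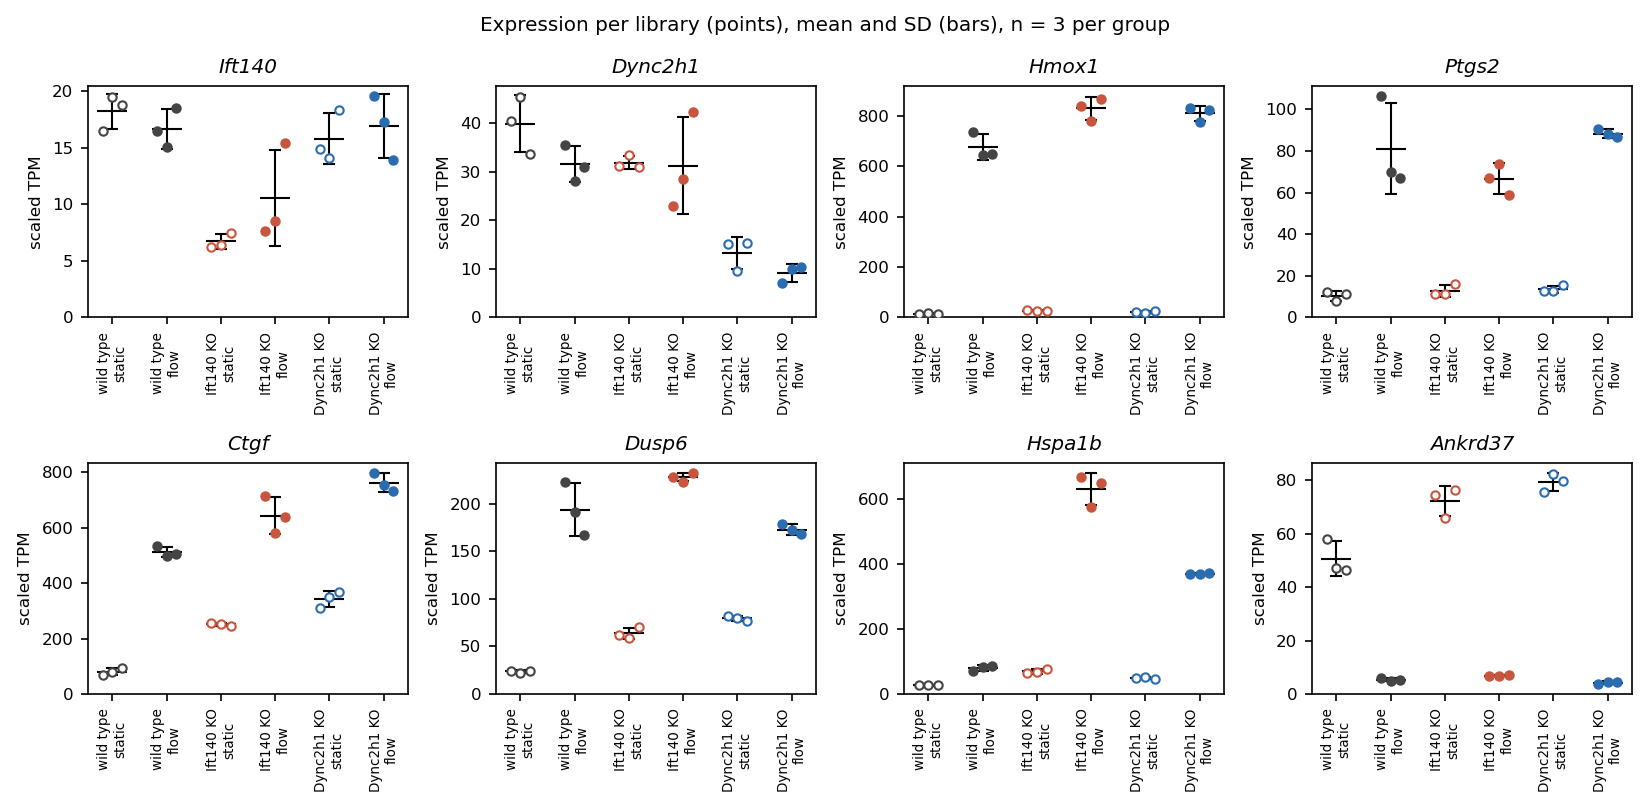
Scaled TPM of 8 genes in each of the 18 libraries, with the mean and SD of each group of 3.

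Flow against static in wild-type cells asks for the response of ciliated cells to 3 h of flow. Hmox1 (GRCm38, chromosome 8, 75093621 to 75100589), which encodes a heme-degrading enzyme, rose most, by 5.39 (SE 0.10, 15.2 ± 1.81 to 677 ± 52.4 TPM) with adjusted p = 1.33e-14. Ankrd37 (GRCm38, chromosome 8, 45996902 to 46005707), a hypoxia-induced gene, fell, with a change of -3.02 (SE 0.10, 50.5 ± 6.54 to 5.35 ± 0.5 TPM) with adjusted p = 3.21e-11. Of the 16718 genes tested, 1702 rose and 1727 fell, and 384 of them changed at least 2-fold. Further rises were Areg, a ligand of the EGF receptor, by 3.72 (SE 0.21, 0.0943 ± 0.0889 to 13.6 ± 2.77 TPM), Chac1 by 3.28 (SE 0.14, 4.45 ± 0.476 to 52.1 ± 4.87 TPM), and the phosphatase genes Dusp5 by 3.12 (SE 0.11, 12.6 ± 0.686 to 118 ± 21.2 TPM), Dusp6 (GRCm38, chromosome 10, 99263231 to 99267489) by 2.97 (SE 0.09, 23.6 ± 1.21 to 194 ± 28.1 TPM) and Dusp4 by 2.74 (SE 0.08, 5 ± 0.294 to 39 ± 1.45 TPM). Ptgs2, which encodes an enzyme of prostaglandin synthesis, rose by 2.83 (SE 0.19, 10.5 ± 2.45 to 81.1 ± 21.8 TPM), Plk3 by 2.74 (SE 0.29), Srxn1 by 2.71 (SE 0.10, 14.6 ± 0.597 to 101 ± 0.449 TPM) and Ctgf (GRCm38, chromosome 10, 24595442 to 24598683) by 2.66 (SE 0.10, 81.1 ± 12.7 to 512 ± 19.1 TPM). The next falls were Smtnl2, -2.11 (SE 0.17, 48.9 ± 3.02 to 10.7 ± 2.53 TPM), Rasl11a, -1.95 (SE 0.17), Narf, -1.92 (SE 0.20, 68.2 ± 2.03 to 17.4 ± 2.65 TPM), Dhrs3, -1.87 (SE 0.17, 63.3 ± 6.57 to 16.7 ± 2.5 TPM), Prr15l, -1.75 (SE 0.20), Slc13a2os, -1.71 (SE 0.22), the epithelial transcription factor gene Ehf, -1.50 (SE 0.11, 117 ± 11 to 40.8 ± 5.35 TPM), Tjp3, -1.49 (SE 0.14), and Mkx, -1.49 (SE 0.20).

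In wild-type cells the ERK, immediate early, YAP, SRF and TGF-beta lists passed as higher. Among the ERK feedback and target genes 17 of 19 rose, 0 fell and 2 did not pass (18 adjusted over the list alone), adjusted p = 8.71e-23, with Epha2 up by 1.92 (SE 0.09, 89.8 ± 6.98 to 343 ± 46 TPM) beside Dusp4, Dusp5 and Dusp6. Of the immediate early genes 23 of 31 rose, 1 fell and 7 did not pass (27 adjusted over the list alone), adjusted p = 2.48e-19, with Klf6 at 1.57 (SE 0.08), Atf3 at 2.48 (SE 0.13), Ier2 at 1.696 (SE 0.12) and Junb at 0.91 (SE 0.06). The YAP and TAZ targets rose as a group, adjusted p = 0.00128, where 8 of 20 rose, 1 fell and 11 did not pass (11 adjusted over the list alone). Cyr61 gained 1.53 (SE 0.10, 223 ± 18.9 to 645 ± 41 TPM) and Gadd45a 1.46 (SE 0.13). For the SRF and MRTF cytoskeletal targets 4 of 20 rose, 0 fell and 16 did not pass (7 adjusted over the list alone), adjusted p = 0.00125. Fhl2 lay at 1.39 (SE 0.08) and the actin gene Actg1 at 0.51 (SE 0.08). TGF-beta and BMP targets also rose, adjusted p = 0.000738: 7 of 20 rose, 2 fell and 11 did not pass (9 adjusted over the list alone). Tgif1 lay at 1.42 (SE 0.10) against Smad6 at -1.10 (SE 0.14).

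The NRF2, heat shock, unfolded protein, p53 and NF-kB lists passed as higher too. Of the NRF2 targets, which answer oxidative stress, 16 of 21 rose, 0 fell and 5 did not pass (17 adjusted over the list alone), adjusted p = 5.98e-16. Txnrd1 lay at 2.03 (SE 0.08, 155 ± 6.83 to 639 ± 62.2 TPM) and Gclc at 2.06 (SE 0.11, 80.2 ± 8.58 to 338 ± 32 TPM). Heat shock genes gave adjusted p = 1.04e-07 and 10 of 14 rose, 0 fell and 4 did not pass (11 adjusted over the list alone). Hspa1b (GRCm38, chromosome 17, 34956436 to 34959238) lay at 1.52 (SE 0.09, 27.2 ± 1.69 to 80.5 ± 9.33 TPM) and Dnajb1 at 0.72 (SE 0.08). In the unfolded protein and amino acid stress list 11 of 23 rose, 6 fell and 6 did not pass (18 adjusted over the list alone), adjusted p = 0.000379, and Atf4 gained 1.44 (SE 0.07, 137 ± 4.5 to 373 ± 14.2 TPM) and Trib3 2.06 (SE 0.12). The p53 targets held Gdf15, up by 2.47 (SE 0.09, 84 ± 4.93 to 469.9 ± 42.9 TPM), and Sesn1, at -1.17 (SE 0.09); 8 of 19 rose, 1 fell and 10 did not pass (10 adjusted over the list alone), adjusted p = 0.00119. Among NF-kB and inflammatory targets 8 of 21 rose, 2 fell and 11 did not pass (11 adjusted over the list alone), adjusted p = 0.000427, including Cxcl1 at 2.44 (SE 0.18) and Lif at 1.78 (SE 0.15). Endothelial-type shear response genes rose, adjusted p = 0.000379, with 8 of 16 rose, 1 fell and 7 did not pass (9 adjusted over the list alone) and Plat at 1.55 (SE 0.10, 179 ± 11.6 to 529.7 ± 80.1 TPM). The prostaglandin list, where 4 of 10 rose, 1 fell and 5 did not pass (6 adjusted over the list alone), passed at adjusted p = 0.0245 but not at adjusted p = 0.0881 with an estimated correlation, and its receptor gene Ptger4 rose by 2.30 (SE 0.10, 8.06 ± 0.371 to 43.9 ± 5.7 TPM). Extracellular matrix and protease genes passed at adjusted p = 0.00489, adjusted p = 0.38 with an estimated correlation, and at adjusted p = 0.0843 without wild-type flow replicate 1; 9 of 35 rose, 1 fell and 25 did not pass (11 adjusted over the list alone), among them Plaur at 2.36 (SE 0.14, 33.7 ± 5.78 to 178 ± 38.2 TPM) and Plau at 1.55 (SE 0.10, 67.4 ± 8.4 to 199.8 ± 24.6 TPM).

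The cilium, mitosis, hypoxia and interferon lists passed as lower in wild-type cells, though the interferon list lost its call with an estimated correlation. Most members of the cilium and interferon lists did not pass. Of the BBSome and transition zone genes 14 of 33 fell, 0 rose and 19 did not pass (14 adjusted over the list alone), adjusted p = 5.52e-05. Cc2d2a lay at -1.04 (SE 0.16, 37.2 ± 2.5 to 17.7 ± 2.44 TPM) and Invs at -0.82 (SE 0.15). Among intraflagellar transport genes 6 of 31 fell, 1 rose and 24 did not pass (7 adjusted over the list alone), adjusted p = 0.00129. Ttc30b lay at -0.91 (SE 0.11) and Wdr19 at -0.82 (SE 0.15). Mitosis genes gave adjusted p = 1.67e-10 and 17 of 25 fell, 0 rose and 8 did not pass (19 adjusted over the list alone). Bub1b lay at -0.93 (SE 0.08, 217 ± 6.36 to 114 ± 9.05 TPM) and Nusap1 at -1.02 (SE 0.09). In the hypoxia and glycolysis list 9 of 25 fell, 1 rose and 15 did not pass (12 adjusted over the list alone), adjusted p = 0.00119, and Bnip3 changed by -0.87 (SE 0.11) and Ak4 by -1.10 (SE 0.15). Interferon-stimulated genes fell at adjusted p = 0.00125, adjusted p = 0.38 with an estimated correlation; 6 of 20 fell, 0 rose and 14 did not pass (7 adjusted over the list alone). Ifit3 lay at -1.14 (SE 0.12) and Usp18 at -1.33 (SE 0.32).

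The other lists did not pass in wild-type cells, though single members did. Adjusted p was 0.149 for the Hedgehog pathway, 0.974 for cyst genes and mechanosensitive channels, where Piezo1 rose by 0.72 (SE 0.15), 0.558 for WNT genes, where Wnt4 changed by -0.88 (SE 0.14), and 0.934 for the Notch pathway, where Lfng rose by 1.02 (SE 0.12, 40.1 ± 2.18 to 82.4 ± 8.28 TPM). It was 0.688 for purinergic signalling and cAMP, 0.666 for principal cell markers, where Sgk1 rose by 1.81 (SE 0.18), 0.592 for epithelial identity, where Cldn4 rose by 1.74 (SE 0.11, 155 ± 0.492 to 524 ± 85.1 TPM) and Krt8 by 0.66 (SE 0.07), 0.469 for S phase genes and 0.121 for cholesterol synthesis. Marker lists gave 0.329 (intercalated cells), 0.344 (proximal tubule), 0.245 (thick limb and distal tubule), 0.332 (endothelium), 0.143 (leukocytes) and 0.469 (fibroblasts), and mitochondrially encoded genes gave 0.572. Mean and test differed in sign for the epithelial list (median -0.02, mean -0.01, test up), the Notch pathway (median -0.05, mean -0.00, test up) and principal cell markers (median -0.24, mean 0.001, test down). In the cyst and WNT lists the medians, 0.06 and 0.04, lay above 0 and the means, -0.02 and -0.04, below.

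Flow against static in Ift140 knockout cells asks for the response of that line. Hmox1 rose by 4.90 (SE 0.10, 26.9 ± 2.63 to 829.7 ± 45.6 TPM) with adjusted p = 5.65e-14, and the heat shock genes Hspa1a (GRCm38, chromosome 17, 34969190 to 34972156) and Hspa1b rose by 4.27 (SE 0.13, 1.02 ± 0.136 to 37.9 ± 4.24 TPM) and by 3.17 (SE 0.09, 69.6 ± 7.26 to 632 ± 48.4 TPM). Ankrd37 fell from 72.1 ± 5.62 to 6.83 ± 0.183 TPM, a change of -3.22 (SE 0.10), and the glycolysis gene Eno2 from 16.1 ± 2.21 to 1.86 ± 0.698 TPM, a change of -2.60 (SE 0.17). Of the genes tested 1539 rose and 1383 fell, 339 of them at least 2-fold. On the deposited scaling 1032 rose and 1268 fell, with quantile normalisation 1327 and 1563, and with only these 2 groups in the fit 604 passed. Other large rises were Chac1, 3.01 (SE 0.14, 5.28 ± 1.39 to 48.9 ± 3.05 TPM), Angptl4, 2.68 (SE 0.13, 3.95 ± 0.795 to 30.7 ± 4.12 TPM), Areg, 2.68 (SE 0.21), Dusp5, 2.59 (SE 0.11, 21.4 ± 0.464 to 135 ± 11 TPM), Osgin1, 2.57 (SE 0.29), Ptgs2, 2.30 (SE 0.19, 12.9 ± 2.95 to 66.6 ± 7.51 TPM), and Sgk1, a kinase gene of sodium transport, 2.29 (SE 0.18, 13.1 ± 2.91 to 67.1 ± 2.97 TPM). Falls were Rasl11a, -2.09 (SE 0.17), Prr15l, -2.08 (SE 0.20), Smtnl2, -2.02 (SE 0.17, 65.2 ± 6.4 to 15.6 ± 3.62 TPM), the cyclin gene Ccng2, -1.89 (SE 0.09, 284 ± 23.5 to 75.5 ± 2.44 TPM), the linker histone gene H1f0, -1.73 (SE 0.08, 178 ± 7.42 to 52.9 ± 3.4 TPM), Lpin1, -1.71 (SE 0.14), Narf, -1.64 (SE 0.20), and Dhrs3, -1.50 (SE 0.17).

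Heat shock and NRF2 genes led the lists of the Ift140 knockout. Of the heat shock genes 13 of 14 rose, 0 fell and 1 did not pass (14 adjusted over the list alone), adjusted p = 5.09e-18. Dnajb1 lay at 1.30 (SE 0.08, 71.7 ± 4.31 to 179 ± 17 TPM) and Hsp90aa1 at 0.85 (SE 0.07, 880.4 ± 66.6 to 1591 ± 121 TPM). For NRF2 targets 17 of 21 rose, 0 fell and 4 did not pass (17 adjusted over the list alone), adjusted p = 4.02e-17. Txnrd1 lay at 2.07 (SE 0.08, 113 ± 7.65 to 475 ± 33.5 TPM) and Srxn1 at 2.23 (SE 0.10). ERK feedback and target genes gave adjusted p = 2.6e-16 and 15 of 19 rose, 0 fell and 4 did not pass (15 adjusted over the list alone). Dusp4 lay at 1.87 (SE 0.08), Dusp6 at 1.83 (SE 0.09, 63.6 ± 6.16 to 228 ± 4.72 TPM) and Epha2 at 1.66 (SE 0.09). Of the immediate early genes 18 of 31 rose, 1 fell and 12 did not pass (21 adjusted over the list alone), adjusted p = 2.45e-14. Atf3 lay at 2.20 (SE 0.13) and Klf6 at 1.26 (SE 0.08). The p53 targets passed at adjusted p = 0.0159, where 8 of 19 rose, 2 fell and 9 did not pass (12 adjusted over the list alone). Gdf15 lay at 2.104 (SE 0.09, 79.8 ± 1.81 to 348 ± 37.2 TPM). The unfolded protein list passed at adjusted p = 9.83e-05, adjusted p = 0.0538 with an estimated correlation; 10 of 23 rose, 3 fell and 10 did not pass (15 adjusted over the list alone). Atf4 lay at 1.195 (SE 0.07) and Herpud1 at 1.31 (SE 0.09).

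The hypoxia, cholesterol, mitosis and BBSome and transition zone lists passed as lower in the Ift140 knockout, mitosis not with an estimated correlation. In the hypoxia and glycolysis list 12 of 25 fell, 0 rose and 13 did not pass (12 adjusted over the list alone), adjusted p = 9.15e-08. Ak4 lay at -1.45 (SE 0.15, 9.12 ± 0.48 to 2.71 ± 0.48 TPM) and Hk2 at -0.85 (SE 0.11). Cholesterol synthesis genes gave adjusted p = 5.48e-07 and 11 of 25 fell, 1 rose and 13 did not pass (15 adjusted over the list alone). Hmgcs1 lay at -1.01 (SE 0.07, 210.1 ± 13.9 to 104 ± 4.43 TPM) and Mvd at -0.89 (SE 0.09, 64.5 ± 1.53 to 34.6 ± 3.85 TPM). Of the BBSome and transition zone genes 7 of 33 fell, 0 rose and 26 did not pass (11 adjusted over the list alone), adjusted p = 0.000933. Cc2d2a lay at -0.82 (SE 0.16) and Bbs10 at -0.84 (SE 0.16). The calls of these 2 members ended with only the groups compared in the fit. Mitosis genes passed at adjusted p = 9.15e-08, adjusted p = 0.0538 with an estimated correlation; 12 of 25 fell, 0 rose and 13 did not pass (15 adjusted over the list alone). Bub1b lay at -0.73 (SE 0.08, 171 ± 13.2 to 103 ± 12.4 TPM). The interferon list, where 5 of 20 fell, 0 rose and 15 did not pass (5 adjusted over the list alone), passed at adjusted p = 0.0159 and not at adjusted p = 0.49 with an estimated correlation. Ifit2 lay at -0.65 (SE 0.09).

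Several lists of the Ift140 knockout passed by a small margin. YAP and TAZ targets had adjusted p = 0.0159, adjusted p = 0.126 with an estimated correlation and adjusted p = 0.0648 without the library labelled Ift140 knockout flow replicate 3, and 5 of 20 rose, 1 fell and 14 did not pass (8 adjusted over the list alone). Ctgf lay at 1.35 (SE 0.10, 251 ± 5.74 to 644 ± 67.1 TPM). NF-kB targets had adjusted p = 0.0301, adjusted p = 0.16 with an estimated correlation and adjusted p = 0.0609 without flow replicate 1; 9 of 21 rose, 2 fell and 10 did not pass (12 adjusted over the list alone). Cxcl1 lay at 1.81 (SE 0.18). Prostaglandin genes had adjusted p = 0.0199 and adjusted p = 0.0941 with an estimated correlation; 4 of 10 rose, 0 fell and 6 did not pass (4 adjusted over the list alone). TGF-beta and BMP targets had adjusted p = 0.0478, adjusted p = 0.16 with an estimated correlation and up to 0.0992 with a library left out, and 6 of 20 rose, 2 fell and 12 did not pass (10 adjusted over the list alone). SRF and MRTF targets had adjusted p = 0.048, adjusted p = 0.131 with an estimated correlation and up to 0.088 with a library left out; 4 of 20 rose, 0 fell and 16 did not pass (4 adjusted over the list alone). The Hedgehog pathway had adjusted p = 0.0494, adjusted p = 0.196 with an estimated correlation and up to 0.205 with a library left out; 5 of 8 fell, 0 rose and 3 did not pass (5 adjusted over the list alone). Gas1 lay at -0.69 (SE 0.14). Intraflagellar transport genes did not pass, adjusted p = 0.0596, nor did endothelial-type shear response genes, adjusted p = 0.124, or extracellular matrix genes, adjusted p = 0.295, though Plaur rose by 1.99 (SE 0.14, 36.7 ± 3.25 to 149 ± 13.8 TPM). The mitochondrial gene mt-Co2 changed from 13.5 ± 5.73 TPM and was listed at 0 under flow.

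Flow against static in Dync2h1 knockout cells asks the same of the other line. Hmox1 rose by 5.14 (SE 0.10, 22.1 ± 2.87 to 811 ± 29.3 TPM) with adjusted p = 2.72e-14, Areg by 4.29 (SE 0.21, 3.42 ± 0.933 to 83.9 ± 2.23 TPM) and the chemokine gene Cxcl1 by 3.01 (SE 0.18, 14.1 ± 0.881 to 122 ± 24.6 TPM). Ankrd37 changed by -3.94 (SE 0.10, 79.3 ± 3.39 to 4.23 ± 0.525 TPM) with adjusted p = 1.11e-12. Of the genes tested 1810 rose and 1363 fell, 346 of them at least 2-fold. On the deposited scaling 830 rose and 1761 fell, and with quantile normalisation 1346 and 1421. Further rises were Hspa1a, 2.90 (SE 0.13, 0.626 ± 0.11 to 11.1 ± 0.577 TPM), Hspa1b, 2.90 (SE 0.09, 48.8 ± 2.52 to 369.8 ± 2.26 TPM), Srxn1, 2.64 (SE 0.10, 14.9 ± 0.891 to 98.2 ± 3.36 TPM), Ptgs2, 2.61 (SE 0.19, 13.7 ± 1.67 to 88.4 ± 1.99 TPM), Dusp5, 2.50 (SE 0.11, 27.6 ± 2.6 to 161 ± 11.3 TPM), the AP-1 gene Fosl1, 2.40 (SE 0.18), and Gclc, 2.36 (SE 0.11, 55.7 ± 6.87 to 288 ± 15.4 TPM). Falls were Mir1843b, -3.18 (SE 0.73), Smtnl2, -2.55 (SE 0.17, 53 ± 1.97 to 8.27 ± 1.34 TPM), Dhrs3, -2.30 (SE 0.17, 32.4 ± 1.22 to 5.93 ± 1.66 TPM), Lpin1, -2.05 (SE 0.14, 31.4 ± 3.38 to 6.83 ± 0.627 TPM), H1f0, -2.05 (SE 0.08, 192 ± 8.15 to 45.7 ± 3.45 TPM), Eno2, -1.95 (SE 0.17, 14.2 ± 2.74 to 2.9 ± 0.275 TPM), Smad6, an inhibitor gene of BMP signalling, -1.92 (SE 0.14, 10.2 ± 0.935 to 1.97 ± 0.223 TPM), Mab21l3, -1.86 (SE 0.21), and Slc13a2os, -1.83 (SE 0.22).

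Immediate early, heat shock and NRF2 genes rose in the Dync2h1 knockout. Of the immediate early genes 21 of 31 rose, 0 fell and 10 did not pass (27 adjusted over the list alone), adjusted p = 1.73e-18. Klf6 lay at 1.63 (SE 0.08, 59.2 ± 2.96 to 185 ± 14.1 TPM) and Dusp2 at 2.27 (SE 0.17). Heat shock genes gave adjusted p = 1.86e-17 and 13 of 14 rose, 0 fell and 1 did not pass (13 adjusted over the list alone). Hsp90aa1 lay at 1.00 (SE 0.07, 966 ± 2 to 1938 ± 6.51 TPM). For NRF2 targets 15 of 21 rose, 0 fell and 6 did not pass (18 adjusted over the list alone), adjusted p = 1.74e-16. Txnrd1 lay at 1.79 (SE 0.08, 143 ± 8.49 to 498 ± 29.3 TPM). Of the ERK feedback and target genes 13 of 19 rose, 0 fell and 6 did not pass (13 adjusted over the list alone), adjusted p = 1.34e-12. Dusp4 lay at 1.66 (SE 0.08) and Epha2 at 1.69 (SE 0.09, 142 ± 12 to 460.2 ± 15.7 TPM). NF-kB and inflammatory targets passed at adjusted p = 3.53e-05, where 12 of 21 rose, 3 fell and 6 did not pass (17 adjusted over the list alone). Cxcl2 lay at 3.42 (SE 0.20, 0.99 ± 0.162 to 20.6 ± 5.15 TPM), Csf2 at 1.94 (SE 0.19) and Lif at 1.83 (SE 0.15). The unfolded protein list gave adjusted p = 8.76e-05 and 11 of 23 rose, 1 fell and 11 did not pass (12 adjusted over the list alone). Chac1 lay at 1.94 (SE 0.14, 12.9 ± 1.7 to 52.4 ± 4.21 TPM). Among p53 targets 7 of 19 rose, 1 fell and 11 did not pass (9 adjusted over the list alone), adjusted p = 0.00878. Gdf15 lay at 2.27 (SE 0.09, 100.2 ± 7.27 to 486 ± 33.5 TPM). Endothelial-type shear response genes passed at adjusted p = 0.00878; 8 of 16 rose, 4 fell and 4 did not pass (12 adjusted over the list alone). Plat lay at 1.38 (SE 0.10, 312 ± 13.4 to 810 ± 34.4 TPM). Prostaglandin genes passed at adjusted p = 0.011, adjusted p = 0.0574 with an estimated correlation; 4 of 10 rose, 0 fell and 6 did not pass (4 adjusted over the list alone). Ptger4 lay at 1.90 (SE 0.10).

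The hypoxia and cholesterol lists passed as lower in the Dync2h1 knockout. For hypoxia and glycolysis 12 of 25 fell, 0 rose and 13 did not pass (12 adjusted over the list alone), adjusted p = 4.05e-08. Ak4 lay at -1.76 (SE 0.15, 23 ± 4.29 to 6.06 ± 0.867 TPM) and Bnip3 at -1.004 (SE 0.11, 82.8 ± 5.24 to 40.8 ± 2.74 TPM). Of the cholesterol synthesis genes 13 of 25 fell, 0 rose and 12 did not pass (14 adjusted over the list alone), adjusted p = 4.05e-08. Hmgcs1 lay at -1.24 (SE 0.07, 176 ± 12.6 to 74.1 ± 4.68 TPM) and Insig1 at -0.76 (SE 0.09, 278 ± 13.7 to 164 ± 3.58 TPM). The BBSome and transition zone list passed at adjusted p = 0.0014, where 4 of 33 fell, 0 rose and 29 did not pass (3 adjusted over the list alone). Cc2d2a lay at -1.34 (SE 0.16, 13.8 ± 2.53 to 4.85 ± 0.815 TPM). Mitosis genes passed at adjusted p = 6.1e-06, adjusted p = 0.0814 with an estimated correlation; 12 of 25 fell, 1 rose and 12 did not pass (17 adjusted over the list alone). Aurkb lay at -0.64 (SE 0.10). Intraflagellar transport genes passed at adjusted p = 0.0263, adjusted p = 0.0574 with an estimated correlation and adjusted p = 0.0639 without flow replicate 1; 2 of 31 fell, 0 rose and 29 did not pass (2 adjusted over the list alone). Ttc30b lay at -0.85 (SE 0.11). The interferon list passed at adjusted p = 0.0287, adjusted p = 0.479 with an estimated correlation and adjusted p = 0.762 without flow replicate 2; 4 of 20 fell, 0 rose and 16 did not pass (4 adjusted over the list alone). Ifit1 lay at -1.22 (SE 0.15). YAP and TAZ targets (adjusted p = 0.172), SRF and MRTF targets (adjusted p = 0.46), TGF-beta and BMP targets (adjusted p = 0.983) and the Hedgehog pathway (adjusted p = 0.172) did not pass, though Ctgf rose by 1.15 (SE 0.10, 344 ± 29.6 to 763 ± 33.2 TPM), and the TGF-beta list had a median of 0.01, a mean of -0.04 and an upward test.

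The flow responses of the 3 lines overlapped in part. In all of them 846 genes rose, 635 fell and 6 passed with mixed direction, and 95 of the rises and 44 of the falls were at least 2-fold in each line. Hmox1, Ptgs2, Dusp5, Areg and Hspa1b were among the shared rises and Ankrd37, Smtnl2 and Dhrs3 among the shared falls. Wild type shared 1957 calls of the same sign with the Ift140 knockout (5 opposite) and 1979 with the Dync2h1 knockout (12 opposite), and the knockouts shared 1780 (5 opposite). For the first pair, 157 shared rises and 143 shared falls would fall together if calls were independent, against 1041 and 916 found. Fold changes over all genes correlated at r = 0.56, 0.57 and 0.55, and 2509 of the 5273 genes that passed anywhere did so in a single line. A call in a single line does not show that the responses differ. Direct tests of the difference from wild type, which found fewer of the simulated changes, called 38 genes for the Ift140 knockout and 81 for the Dync2h1 knockout.

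**Figure D2:**
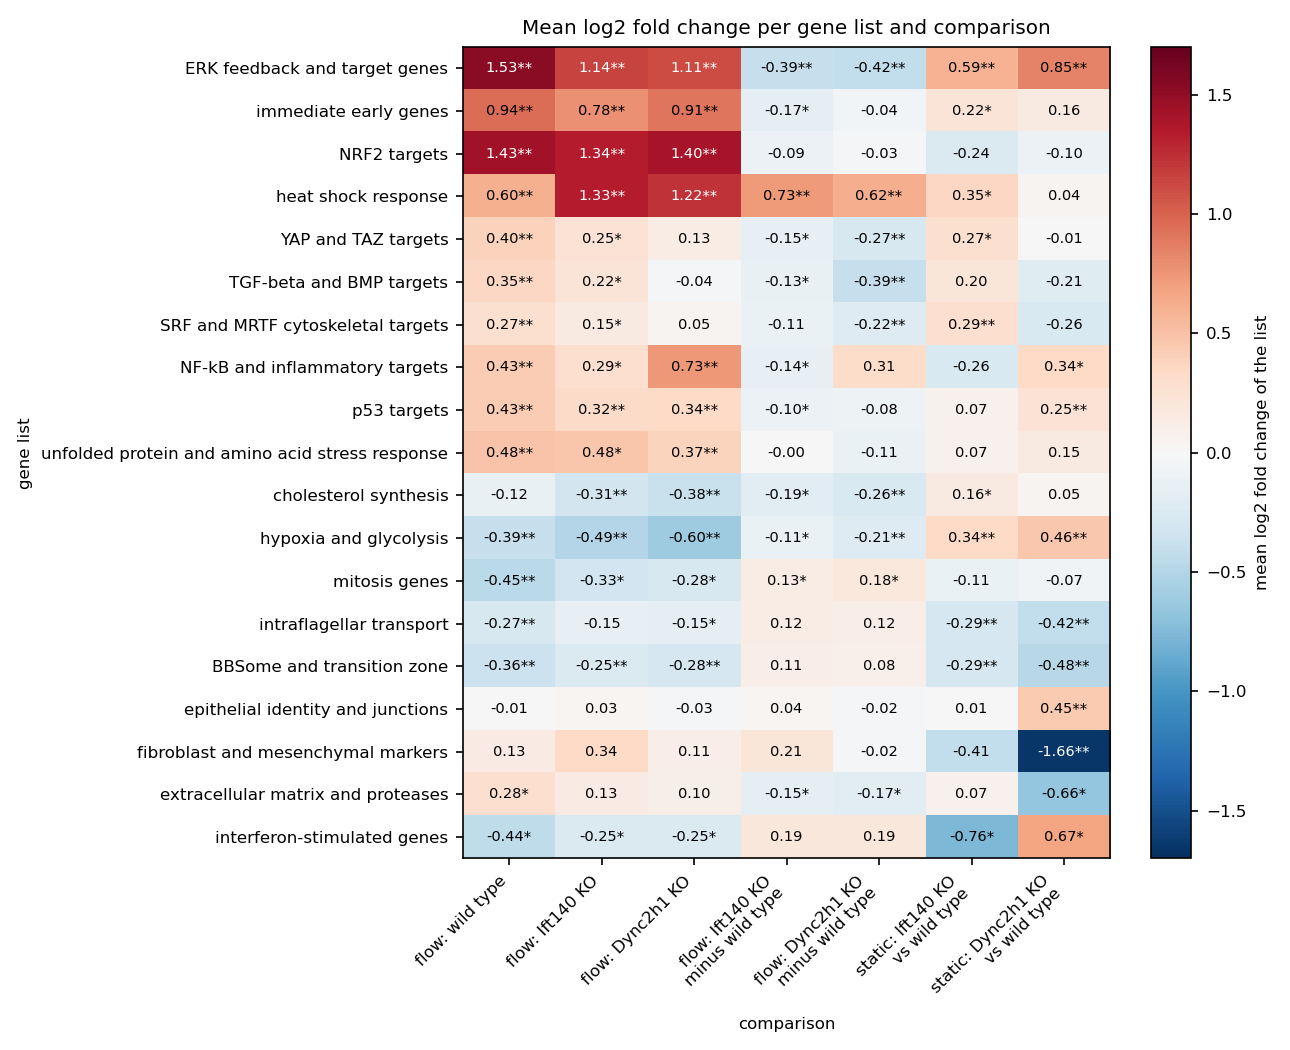
Mean log2 fold change of the measured members of 19 gene lists in 7 comparisons. A star marks an adjusted p under 0.05 at the preset correlation, and a pair of stars marks lists that also passed with an estimated correlation.

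The difference between the flow responses of Ift140 knockout and wild-type cells asks which changes depend on the line. The heat shock genes Hspa1a and Hspa1b rose more in the knockout, by 2.42 (SE 0.18) with adjusted p = 1.37e-05 and by 1.64 (SE 0.13) with adjusted p = 1.37e-05. On the log2 scale Ctgf rose less, -1.31 (SE 0.14) with adjusted p = 0.00073, as did Plau, -1.18 (SE 0.15), Dusp6, -1.14 (SE 0.13), and Kctd11, -1.01 (SE 0.14). In TPM, Ctgf rose by 392 in the knockout against 431 in wild type, and Dusp6 by 164 against 170. Both started higher in the static knockout, at 251 against 81.1 TPM and at 63.6 against 23.6 TPM. Plau rose by 33 TPM against 132 and Kctd11 by 3.64 against 10.5. Of the genes tested 13 were higher and 25 lower in this difference. The deposited scaling gave 4 and 15, the fit with only the groups compared 3 and 3, library weights 37 and 41, and a 2-fold threshold 7 and 7, so the excess of lower genes depended on the setting. Calls that ended under other settings were Tmem181c-ps, 1.71 (SE 0.31), Kank3, 0.89 (SE 0.14), Acot2, 0.83 (SE 0.13), Zfp266, 0.81 (SE 0.15), and Eno2, -1.28 (SE 0.24), each on the deposited scaling, and the keratin gene Krt17, -1.10 (SE 0.19), with only the groups compared. Hspa1a and Hspa1b are near-identical in sequence, so how reads were split between them is uncertain.

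By list, heat shock genes were higher in the Ift140 difference: 3 of 14 higher, 0 lower and 11 did not pass (11 adjusted over the list alone), adjusted p = 1.66e-18. ERK feedback and target genes were lower, with 3 of 19 lower and 16 not passing (10 adjusted over the list alone), adjusted p = 3.55e-12, and endothelial-type shear response genes were lower as a group, adjusted p = 1.53e-05, with 0 of 16 passing (5 adjusted over the list alone). Lower as well were immediate early genes (adjusted p = 9.62e-05, adjusted p = 0.135 with an estimated correlation), cholesterol synthesis (adjusted p = 3.53e-06, adjusted p = 0.0902 with an estimated correlation) and TGF-beta and BMP targets (adjusted p = 0.00773, adjusted p = 0.133 with an estimated correlation). The same held for hypoxia and glycolysis (adjusted p = 0.0101, adjusted p = 0.133 with an estimated correlation) and p53 targets (adjusted p = 0.0214, adjusted p = 0.0902 with an estimated correlation). So it did for YAP and TAZ targets (adjusted p = 0.0133, adjusted p = 0.138 with an estimated correlation), NF-kB targets (adjusted p = 0.0133, adjusted p = 0.14 with an estimated correlation) and extracellular matrix genes (adjusted p = 0.00451, adjusted p = 0.313 with an estimated correlation). Mitosis genes were higher, adjusted p = 0.00844, adjusted p = 0.304 with an estimated correlation. Leaving out a library ended the calls of TGF-beta (0.109), hypoxia (0.086), p53 (0.0924), YAP (0.0942), NF-kB (0.0673), extracellular matrix (0.215) and mitosis genes (0.137), where the values are the highest adjusted p.

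The difference between the flow responses of Dync2h1 knockout and wild-type cells held more genes. Dusp6 rose less in the knockout, -1.86 (SE 0.13) with adjusted p = 3.66e-06, and the Notch modifier gene Lfng, which rose in wild type, fell in the knockout (-0.73 (SE 0.12)), a difference of -1.75 (SE 0.18) with adjusted p = 0.000119. The GTPase gene Rrad rose more, 1.72 (SE 0.13) with adjusted p = 6.16e-06, as did the chemokine gene Ccl20, 1.98 (SE 0.29), Hspa1b, 1.37 (SE 0.13), and Nfkbia, 1.28 (SE 0.21). Of the genes tested 30 were higher and 51 lower, and the excess of lower genes depended on the setting. The deposited scaling gave 13 and 50, the fit with only the groups compared 81 and 71, library weights 178 and 139, and the fit without the library labelled Ift140 knockout flow replicate 3 gave 79 and 81. Also lower were Ctgf, -1.50 (SE 0.14), Chac1, -1.34 (SE 0.19), Kctd11, -1.27 (SE 0.14), and Lpin1, -1.22 (SE 0.20). In TPM, Ctgf rose by 419 in this knockout against 431 in wild type. Dusp6 rose by 93.3 TPM against 170 and Kctd11 by 2.34 against 10.5. Hspa1a, 1.05 (SE 0.18), and Rasl11a, 1.22 (SE 0.24), were higher, but their calls ended on the deposited scaling.

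Heat shock genes were again higher in the Dync2h1 difference: 7 of 14 higher, 0 lower and 7 did not pass (10 adjusted over the list alone), adjusted p = 1.25e-16. Lower lists were ERK feedback and target genes (5 of 19 lower, 9 adjusted over the list alone, adjusted p = 3.3e-11), TGF-beta and BMP targets (2 of 20 lower, 8 adjusted over the list alone, adjusted p = 6.81e-09) and cholesterol synthesis (4 of 25 lower, 8 adjusted over the list alone, adjusted p = 1.39e-07). So were hypoxia and glycolysis (adjusted p = 7.44e-05), YAP and TAZ targets (adjusted p = 0.000154) and SRF and MRTF targets (adjusted p = 0.00026). Mitosis genes were higher, adjusted p = 0.00026, adjusted p = 0.201 with an estimated correlation. Weaker calls were mitochondrially encoded genes (adjusted p = 0.00519, adjusted p = 0.291 with an estimated correlation) and endothelial markers (adjusted p = 0.00976, adjusted p = 0.0846 with an estimated correlation). Extracellular matrix genes (adjusted p = 0.0137, adjusted p = 0.378 with an estimated correlation) and WNT genes (adjusted p = 0.0372, adjusted p = 0.259 with an estimated correlation) also passed weakly. Leaving out a library ended the calls of the mitochondrial (0.0564), extracellular matrix (0.368) and WNT (0.128) lists.

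Taken as the mean of both knockouts, 25 genes rose more or fell less than in wild type and 45 the reverse, and the deposited scaling gave 14 and 42. Without the library labelled Ift140 knockout flow replicate 3 the numbers were 68 and 72, and with library weights 96 and 89, so the excess of lower genes did not hold there. Hspa1a, 1.74 (SE 0.16), and Hspa1b, 1.51 (SE 0.11) with adjusted p = 6.01e-06, were higher, as were Rrad, 0.85 (SE 0.11), and the interferon-stimulated gene Ifit3, 0.85 (SE 0.14). The mean of Rrad came from the Dync2h1 knockout, at 1.72 against -0.026 (adjusted p = 0.979) in the Ift140 knockout. Ccl20, 1.28 (SE 0.25), and Kank3, 0.81 (SE 0.12), lost their calls on the deposited scaling. Ccl20 did not pass in the Ift140 knockout, at 0.58 (adjusted p = 0.659). Lower were Dusp6, -1.50 (SE 0.11) with adjusted p = 6.01e-06, Ctgf, -1.41 (SE 0.12), Lfng, -1.295 (SE 0.15), Kctd11, -1.14 (SE 0.12), Plau, -1.10 (SE 0.13), and Lpin1, -1.05 (SE 0.17). Of the lists, heat shock (adjusted p = 4.99e-22) was higher, and ERK targets (adjusted p = 1.26e-14), cholesterol synthesis (adjusted p = 1.6e-08), TGF-beta targets (adjusted p = 2.29e-07), hypoxia (adjusted p = 7.42e-05) and YAP targets (adjusted p = 0.000343) were lower. Endothelial-type shear response genes (adjusted p = 0.000509), SRF targets (adjusted p = 0.0011) and p53 targets (adjusted p = 0.0139) were lower too. Mitosis genes (adjusted p = 0.000212, adjusted p = 0.181 with an estimated correlation) were higher, and immediate early genes (adjusted p = 0.00266, adjusted p = 0.218 with an estimated correlation), extracellular matrix (adjusted p = 0.00153, adjusted p = 0.316 with an estimated correlation), endothelial markers (adjusted p = 0.0117, adjusted p = 0.0815 with an estimated correlation) and WNT genes (adjusted p = 0.0411, adjusted p = 0.251 with an estimated correlation) lower. NF-kB targets did not pass, adjusted p = 0.686, and their median of -0.04 and mean of 0.08 differ in sign.

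In both differences 20 genes passed, 5 higher and 15 lower, none with opposite sign. Hspa1a, Hspa1b, Dusp6 and Ctgf are among them. Because both share the 6 wild-type libraries, simulated groups without change gave r = 0.46 against the 0.50 found and a covariance of 0.0634 against 0.0817. In those draws 0 genes passed in both. The draws hold no real change, so that count could hardly differ from 0. It cannot show how many of the 20 shared calls the shared libraries added. The 45 genes lower in the mean difference lay at a median of 0.52 above wild type in the static knockouts and at -0.12 under flow, and 40 of them rose in wild type.

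Ift140 knockout against wild type in static culture asks how that line differs before flow. The collagen chaperone gene Serpinh1 (GRCm38, chromosome 7, 99345376 to 99353239) fell from 115 ± 6.28 to 0.132 ± 0.0284 TPM, a change of -6.67 (SE 0.08) with adjusted p = 1.46e-17, and Cubn (GRCm38, chromosome 2, 13276338 to 13491813), an endocytic receptor gene, from 409.6 ± 2.69 to 3.28 ± 0.904 TPM, a change of -6.61 (SE 0.16). Ap1m2 (GRCm38, chromosome 9, 21294275 to 21312337), a sorting adaptor gene of epithelial cells, rose by 3.99 (SE 0.12, 0.0163 ± 0.0283 to 15.2 ± 2.49 TPM) with adjusted p = 4.95e-12. Of the genes tested 1500 rose and 1518 fell, 451 of them at least 2-fold. The deposited scaling gave 1522 and 1074, and protein-coding genes only 968 and 1485, so the balance depended on the setting. Other rises were Mir705, 2.37 (SE 0.56), Arhgdig, 2.08 (SE 0.15, 4.2 ± 0.989 to 20.6 ± 1.18 TPM), Cd59b, 1.86 (SE 0.25), Lipg, 1.85 (SE 0.18, 7.51 ± 1.86 to 29.4 ± 4.28 TPM), Bst1, 1.84 (SE 0.13, 16.1 ± 2.25 to 59.7 ± 2.99 TPM), Lrp2, the partner receptor of Cubn, 1.84 (SE 0.17, 21.8 ± 1.95 to 80.3 ± 2.86 TPM), Fst, 1.68 (SE 0.08, 69.7 ± 6.47 to 224 ± 13.7 TPM), and Ctgf, 1.63 (SE 0.10, 81.1 ± 12.7 to 251 ± 5.74 TPM). Other falls were Ank2, -4.95 (SE 0.25, 39.5 ± 1.91 to 0.337 ± 0.301 TPM), Grb10, -4.71 (SE 0.13), Pygl, -3.87 (SE 0.15, 19.9 ± 1.27 to 0.437 ± 0.2 TPM), Asph, -3.57 (SE 0.15, 39.8 ± 2.74 to 2.44 ± 0.164 TPM), Usp11, -3.11 (SE 0.40), and Nqo1, -3.02 (SE 0.23, 14.4 ± 2.19 to 0.989 ± 0.812 TPM). Ctf2, 2.38 (SE 0.73), and the small nucleolar RNAs Snord33, -4.98 (SE 1.35), and Snord16a, -4.83 (SE 1.53), lost their calls when single libraries were left out.

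The ERK and hypoxia lists passed as higher and both cilium lists as lower in the static Ift140 knockout, with most cilium members not passing. Of the ERK feedback and target genes 10 of 19 rose, 0 fell and 9 did not pass (13 adjusted over the list alone), adjusted p = 4.95e-09. Ccnd1 lay at 1.45 (SE 0.07, 10.3 ± 0.229 to 29.9 ± 1.82 TPM) and Dusp6 at 1.39 (SE 0.09, 23.6 ± 1.21 to 63.6 ± 6.16 TPM). In the hypoxia and glycolysis list 15 of 25 rose, 2 fell and 8 did not pass (19 adjusted over the list alone), adjusted p = 1.32e-05. Hk2 lay at 1.11 (SE 0.11) and Vegfa at 0.79 (SE 0.10) against Egln3 at -1.84 (SE 0.11). SRF and MRTF targets gave adjusted p = 0.00147 and 5 of 20 rose, 0 fell and 15 did not pass (6 adjusted over the list alone). Fhl1 lay at 1.41 (SE 0.14, 20.6 ± 2.32 to 56.1 ± 2.48 TPM). Intraflagellar transport genes (5 of 31 fell, 0 rose and 26 did not pass (8 adjusted over the list alone), adjusted p = 0.000411) and BBSome and transition zone genes (6 of 33 fell, 0 rose and 27 did not pass (7 adjusted over the list alone), adjusted p = 0.00127) fell. Wdr19 lay at -0.90 (SE 0.15, 51 ± 4.22 to 27.4 ± 6.82 TPM) and Cc2d2a at -1.12 (SE 0.16, 37.2 ± 2.5 to 16.6 ± 1.71 TPM). Interferon-stimulated genes fell at adjusted p = 5.17e-05, adjusted p = 0.271 with an estimated correlation; 9 of 20 fell, 1 rose and 10 did not pass (12 adjusted over the list alone). Gbp2 lay at -2.51 (SE 0.26, 19.9 ± 1.13 to 2.71 ± 0.706 TPM) against Ifit3 at 1.11 (SE 0.12).

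Calls of the static Ift140 knockout that were lost with an estimated correlation came next. Immediate early genes rose at adjusted p = 0.000686, adjusted p = 0.186 with an estimated correlation; 11 of 31 rose, 2 fell and 18 did not pass (16 adjusted over the list alone). Ier3 lay at 1.36 (SE 0.10, 50.3 ± 4.62 to 131 ± 6.24 TPM) and Klf2 at -1.49 (SE 0.17). Heat shock genes had adjusted p = 0.00073 and adjusted p = 0.0532 with an estimated correlation; 7 of 14 rose, 1 fell and 6 did not pass (9 adjusted over the list alone). Hspa1b lay at 1.32 (SE 0.09, 27.2 ± 1.69 to 69.6 ± 7.26 TPM). Cholesterol synthesis genes had adjusted p = 0.0102 and adjusted p = 0.271 with an estimated correlation; 7 of 25 rose, 0 fell and 18 did not pass (8 adjusted over the list alone). Sqle lay at 0.73 (SE 0.07). YAP and TAZ targets had adjusted p = 0.021, adjusted p = 0.186 with an estimated correlation and adjusted p = 0.0531 without Ift140 knockout static replicate 2; 6 of 20 rose, 2 fell and 12 did not pass (10 adjusted over the list alone). Cyr61 lay at 1.25 (SE 0.10, 223 ± 18.9 to 529 ± 19.1 TPM). The Notch pathway had adjusted p = 0.0294, adjusted p = 0.143 with an estimated correlation and adjusted p = 0.0826 without the same library; 4 of 14 rose, 1 fell and 9 did not pass (7 adjusted over the list alone). Jag1 lay at 0.86 (SE 0.13). Endothelial-type shear response genes did not pass, adjusted p = 0.498: the median of 0.34 and the test pointed up and the mean of -0.23 down, with Nqo1, Klf2 and Vcam1, -1.94 (SE 0.13), among 5 falls and 8 rises. The mesenchymal gene Twist1 fell from 5.41 ± 0.266 to 0.089 ± 0.0662 TPM, a change of -2.56 (SE 0.12), while its list did not pass, adjusted p = 0.134.

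Dync2h1 knockout against wild type in static culture gave the larger set of differences. The intermediate filament gene Vim (GRCm38, chromosome 2, 13573927 to 13582826) fell from 272 ± 5.38 to 4.02 ± 0.709 TPM, a change of -5.77 (SE 0.12) with adjusted p = 2.01e-14, and Cubn from 409.6 ± 2.69 to 3.98 ± 0.333 TPM, a change of -6.37 (SE 0.16). Ap1m2 rose by 6.24 (SE 0.12, 0.0163 ± 0.0283 to 76.1 ± 4.83 TPM) with adjusted p = 2.01e-14, and the cyclin gene Ccnd1 (GRCm38, chromosome 7, 144929931 to 144939925) by 2.85 (SE 0.07, 10.3 ± 0.229 to 80.8 ± 3.53 TPM). Of the genes tested 2255 rose and 2363 fell, 837 of them at least 2-fold. Without chromosomes 1, 5, 6 and 17 the numbers were 1829 and 1239, and for protein-coding genes only 1421 and 2181, so here too the balance depended on the setting. Other rises were Ripk3, 3.48 (SE 0.23, 0.209 ± 0.259 to 12.4 ± 1.74 TPM), Prss22, 2.86 (SE 0.13, 4.14 ± 0.906 to 36.1 ± 2.7 TPM), Apln, 2.70 (SE 0.12, 1.41 ± 0.234 to 14.7 ± 0.377 TPM), Sap18, 2.48 (SE 0.11, 6.02 ± 0.86 to 37.9 ± 3.88 TPM), Plekhs1, 2.39 (SE 0.18), the epithelial GTPase gene Rab25, 2.35 (SE 0.21, 9.14 ± 2.23 to 50 ± 6.21 TPM), and Procr, 2.31 (SE 0.17). Other falls were Igfbp2, -5.53 (SE 0.15, 55.9 ± 6.48 to 0.24 ± 0.199 TPM), Ank2, -5.24 (SE 0.25), Grb10, -4.74 (SE 0.13), the basement membrane collagen genes Col4a2, -4.56 (SE 0.20, 36.7 ± 2.07 to 0.631 ± 0.381 TPM), and Col4a1, -4.24 (SE 0.17, 52.4 ± 5.87 to 1.87 ± 0.732 TPM), Enpep, -4.32 (SE 0.21, 34.5 ± 4.7 to 0.84 ± 0.592 TPM), and the smooth muscle actin gene Acta2, -4.20 (SE 0.19, 20.1 ± 3.72 to 0.142 ± 0.147 TPM). Pygl went from 19.9 ± 1.27 TPM and Panx1 from 6.64 ± 1.02 TPM to being listed at 0. Ctf2, 2.39 (SE 0.73), lost its call when single libraries were left out.

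Epithelial genes stood higher and mesenchymal genes lower in the static Dync2h1 knockout. Of the epithelial identity and junction genes 16 of 28 rose, 0 fell and 12 did not pass (18 adjusted over the list alone), adjusted p = 7.8e-07. Epcam lay at 0.97 (SE 0.10, 193 ± 22.6 to 378 ± 17.3 TPM) and Cldn7 at 0.87 (SE 0.08, 82.5 ± 5.65 to 151 ± 11.5 TPM). For fibroblast and mesenchymal markers 6 of 8 fell, 1 rose and 1 did not pass (7 adjusted over the list alone), adjusted p = 0.000252. Twist1 lay at -2.50 (SE 0.12) and Zeb1 at -2.13 (SE 0.21, 6.59 ± 0.493 to 0.775 ± 0.463 TPM). Intraflagellar transport genes (14 of 31 fell, 0 rose and 17 did not pass (18 adjusted over the list alone), adjusted p = 3.83e-05) and BBSome and transition zone genes (16 of 33 fell, 0 rose and 17 did not pass (17 adjusted over the list alone), adjusted p = 2.28e-05) fell. Ift122 lay at -0.75 (SE 0.10, 42.5 ± 1.31 to 25 ± 1.51 TPM), Ift80 at -0.80 (SE 0.12), Ahi1 at -2.49 (SE 0.16, 9.82 ± 0.871 to 0.922 ± 0.149 TPM) and Arl13b at -0.87 (SE 0.09, 28.8 ± 0.822 to 15.3 ± 0.759 TPM). The list tests were not repeated without chromosomes 1, 5 and 6, whose coding genes lay lower by median in this line. ERK feedback and target genes gave adjusted p = 4.67e-08 and 12 of 19 rose, 0 fell and 7 did not pass (12 adjusted over the list alone). Etv4 lay at 2.25 (SE 0.12, 5.92 ± 0.49 to 32 ± 4.66 TPM) and Dusp6 at 1.71 (SE 0.09). In the hypoxia and glycolysis list 14 of 25 rose, 2 fell and 9 did not pass (18 adjusted over the list alone), adjusted p = 2.28e-05. Slc2a1 lay at 1.30 (SE 0.07, 139 ± 5.34 to 344 ± 5.5 TPM) and Ldha at 0.77 (SE 0.07, 517 ± 16.5 to 884 ± 45.3 TPM). The p53 targets passed at adjusted p = 0.012, where 8 of 19 rose, 2 fell and 9 did not pass (10 adjusted over the list alone). Plk2 lay at 0.99 (SE 0.09, 255 ± 5.87 to 509.7 ± 9.58 TPM). Proximal tubule markers passed at adjusted p = 0.00123, with 2 of 4 measured members falling, Cubn and Lrp2 (-2.06 (SE 0.17, 21.8 ± 1.95 to 4.48 ± 0.365 TPM)).

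Other lists of the static Dync2h1 knockout lost their call with an estimated correlation. Interferon-stimulated genes rose at adjusted p = 0.00075, adjusted p = 0.418 with an estimated correlation; 9 of 20 rose, 1 fell and 10 did not pass (12 adjusted over the list alone). Ifit1 lay at 1.90 (SE 0.15) and Rsad2 at 2.73 (SE 0.28, 0.859 ± 0.19 to 11.5 ± 2.42 TPM). Hedgehog genes fell at adjusted p = 0.00186, adjusted p = 0.0824 with an estimated correlation; 5 of 8 fell, 0 rose and 3 did not pass (5 adjusted over the list alone). Smo lay at -0.78 (SE 0.07, 129.8 ± 4.81 to 75.2 ± 2.03 TPM) and Gas1 at -2.03 (SE 0.14). Falls of these lists too were not tested apart from the lower medians of chromosomes 1, 5 and 6. Extracellular matrix genes had adjusted p = 0.00405 and adjusted p = 0.418 with an estimated correlation; 15 of 35 fell, 8 rose and 12 did not pass (27 adjusted over the list alone). Lama1 lay at -3.66 (SE 0.27, 12.9 ± 2.43 to 0.0962 ± 0.167 TPM) against Plau at 1.93 (SE 0.10, 67.4 ± 8.4 to 258 ± 14.8 TPM). NF-kB targets had adjusted p = 0.0081 and adjusted p = 0.132 with an estimated correlation; 9 of 21 rose, 2 fell and 10 did not pass (12 adjusted over the list alone). Lcn2 lay at 1.58 (SE 0.14, 17.4 ± 1.98 to 54 ± 4.01 TPM). S phase genes had adjusted p = 0.0344, adjusted p = 0.389 with an estimated correlation and adjusted p = 0.0761 without Dync2h1 knockout static replicate 1; 9 of 23 fell, 1 rose and 13 did not pass (10 adjusted over the list alone). Mcm6 lay at -0.65 (SE 0.07, 517 ± 23.5 to 328 ± 10.6 TPM). Principal cell markers had adjusted p = 0.0495, adjusted p = 0.132 with an estimated correlation and adjusted p = 0.0605 without the same library; 5 of 7 fell, 1 rose and 1 did not pass (6 adjusted over the list alone). Atp1b1 lay at -0.67 (SE 0.09, 39.9 ± 4.34 to 24.7 ± 0.78 TPM). YAP and TAZ targets did not pass, adjusted p = 0.866, with a median of -0.18 and an upward test, 8 rises such as Ctgf at 2.08 (SE 0.10, 81.1 ± 12.7 to 344 ± 29.6 TPM) and 7 falls such as Ptpn14 at -1.12 (SE 0.14).

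The static knockouts shared 1668 genes that passed, 813 higher in both, 700 lower in both and 155 with opposite signs. Ap1m2, Ctgf, Ccnd1 and Dusp6 were higher in both and Cubn, Ank2, Grb10 and Twist1 lower in both, while Lrp2 and Col4a1 (Ift140 knockout 1.08 (SE 0.17)) took opposite directions. Independent calls would give 202 shared rises and 215 shared falls. Both comparisons use the same 3 wild-type libraries: simulated groups without change gave r = 0.48 against the 0.52 found, but a covariance of 0.0333 against 0.140. In those draws 0 genes passed in both, a count that draws without real change could hardly exceed. It cannot show how many shared calls the shared libraries added.

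By chromosome, the coding genes of chromosome 17 had a median of 0.37 in the static Ift140 knockout, and in the static Dync2h1 knockout those of chromosomes 1, 6 and 5 had medians of -0.45, -0.45 and -0.25. On chromosome 5 of the Dync2h1 knockout 111 genes rose and 292 fell. On chromosomes 1 and 6 of that line 375 and 312 genes fell, against 91 and 78 that rose. On chromosome 17 of the Ift140 knockout 241 genes rose and 17 fell. The list tests were not repeated without these chromosomes, so list results of the knockouts against wild type are not told apart from the shifts.

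**Figure D3:**
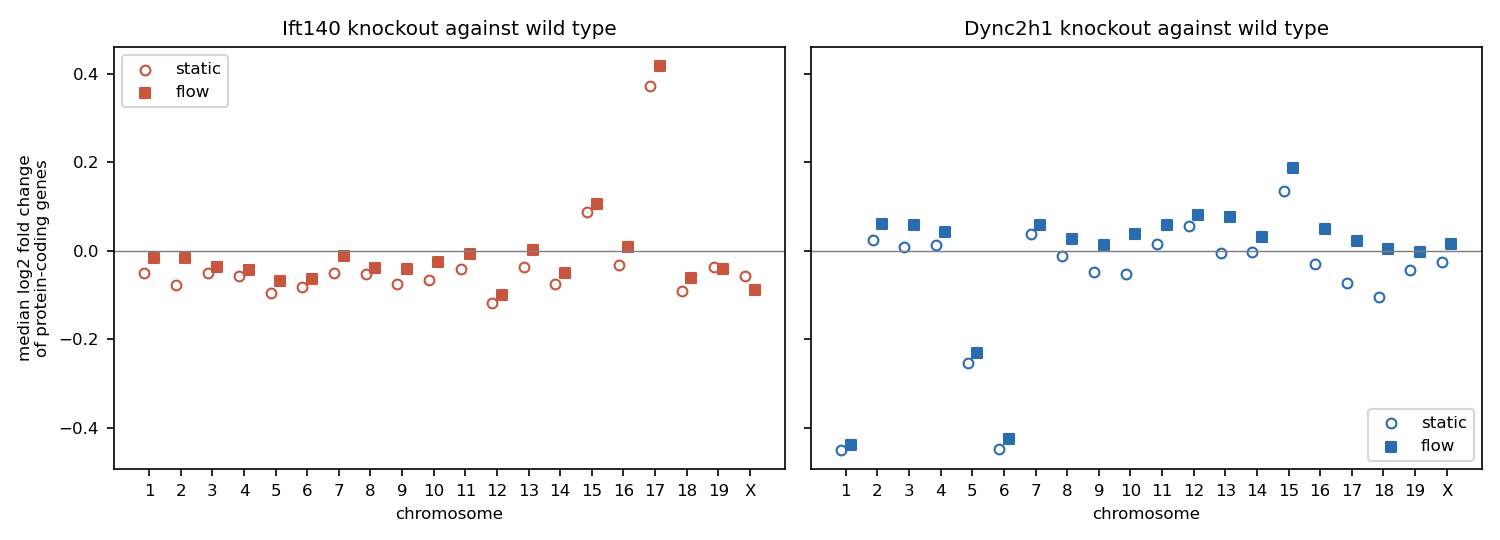
Median log2 fold change of the coding genes of each chromosome for each knockout against wild type, static (open) and under flow (filled).

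Under flow, 1292 genes were higher and 1258 lower in the Ift140 knockout than in wild type, with 616 in all when only these 2 groups were in the fit. In the Dync2h1 knockout 2697 were higher and 2334 lower, and on the deposited scaling 1529 and 2923. Of the genes that passed in static culture, 1550 of the Ift140 knockout passed under flow with the same sign and 9 with the opposite sign, and 3219 and 16 of the Dync2h1 knockout.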

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

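Tests chosen only after the results had been seen are the splits with additive effects removed, the draws without replacement, the draws with line differences kept, the comparison of TPM rises, the wider gene criterion for wild-type RNA and the chromosome test without the end of chromosome 6. All values of the next 3 paragraphs stand out because a test of a difference between flow responses passed. The last of these paragraphs sets the mean response of both knockouts against wild type.

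In the Ift140 knockout against wild type, 38 genes differed in their response. Higher were Hspa1a 2.42, Tmem181c-ps 1.71, Hspa1b 1.64, Kank3 0.89, Acot2 0.835 and Zfp266 0.81, and lower were Ctgf -1.31, Eno2 -1.28, Plau -1.18, Dusp6 -1.14, Krt17 -1.10 and Kctd11 -1.01. List means were 0.73 for heat shock and 0.13 for mitosis genes, and -0.39 for ERK targets, -0.30 for endothelial-type shear genes, -0.19 for cholesterol synthesis, -0.17 for immediate early genes, -0.15 for YAP targets, -0.15 for extracellular matrix, -0.14 for NF-kB targets, -0.13 for TGF-beta targets, -0.11 for hypoxia genes and -0.10 for p53 targets. With an estimated correlation 3 of these 12 lists kept their call, namely heat shock, ERK and shear genes. With genotype labels permuted within static and within flow libraries, 13 of 100 splits, the real order included, gave at least as many genes, up to 5024. Such splits mix the lines, so their high counts point to the structure of the samples. With additive effects of line and flow removed, only the real order, 1 of 100, reached the count, and the highest other gave 3.

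In the Dync2h1 knockout against wild type, 81 genes differed. Higher were Ccl20 1.98, Rrad 1.72, Hspa1b 1.37, Nfkbia 1.28, Rasl11a 1.215 and Hspa1a 1.05, and lower were Dusp6 -1.86, Lfng -1.745, Ctgf -1.505, Chac1 -1.34, Kctd11 -1.27 and Lpin1 -1.22. List means were 0.62 for heat shock and 0.18 for mitosis genes, and -0.55 for endothelial markers, -0.42 for ERK targets, -0.39 for TGF-beta targets, -0.33 for mitochondrially encoded genes, -0.27 for YAP targets, -0.26 for cholesterol synthesis, -0.22 for SRF targets, -0.215 for hypoxia genes, -0.175 for extracellular matrix and -0.14 for WNT genes. With an estimated correlation 7 of these 12 lists kept their call, while mitosis, endothelial, mitochondrial, matrix and WNT genes lost it, and the endothelial list has 2 measured members of 10. Of 100 permuted splits 13 gave as many genes, up to 6944, which again points to sample structure. With additive effects removed it was 1 of 100, and the highest other gave 2.

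In the mean of both knockouts 70 genes differed. Higher were Hspa1a 1.74, Hspa1b 1.51, Ccl20 1.28, Rrad 0.85, Ifit3 0.85 and Kank3 0.81, and lower were Dusp6 -1.50, Ctgf -1.41, Lfng -1.295, Kctd11 -1.14, Plau -1.10 and Lpin1 -1.05. Of these, Ccl20, Rrad, Ifit3, Lfng and Lpin1 passed in the Dync2h1 difference and not in the Ift140 difference. List means were 0.67 for heat shock and 0.15 for mitosis genes, and -0.44 for endothelial markers, -0.41 for ERK targets, -0.26 for TGF-beta targets, -0.22 for cholesterol synthesis, -0.21 for YAP targets, -0.19 for endothelial-type shear genes, -0.165 for SRF targets, -0.16 for extracellular matrix, -0.16 for hypoxia genes, -0.10 for immediate early genes, -0.10 for WNT genes and -0.094 for p53 targets. With an estimated correlation 9 of these 14 lists kept their call, while mitosis, endothelial, matrix, immediate early and WNT genes lost it. Of 100 permuted splits 2 gave as many genes, up to 2729, and with additive effects removed 2 of 100, up to 238.

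Genes lower in the mean difference, most of which rose in wild type and some of which, such as Lpin1, fell further in the knockouts, lay higher in the static knockouts: of the 45 genes 41 did, at a median of 0.52, and 28 passed as higher in both lines. Chance values of the static wild-type libraries that both comparisons share could give such a median, since 7 of 100 simulated draws without any effect, and 6 of 100 without replacement, reached it, up to 0.761 and 0.715. With the line differences kept, 1 of 100 draws with replacement and 1 of 100 without gave at least as many as the 28 genes, up to 32 and 33. Such a count was thus rare in draws without a difference in response but is not excluded, and this form of the test was chosen after the first. The pseudocount does not account for the pattern, since 95.6% of the genes stayed lower with 0.1, and an equal TPM rise over a higher static level does not account for the set, since the 40 genes that rose in wild type kept a median of 39.8% of that rise (SE 10.1), although Ctgf kept 94%. Whether the raised static level causes the smaller rise was not tested.

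For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05, and only the real split, 1 of 10, reached the real count in each. The highest other split gave 1 gene for flow in wild type, 7 for flow in the Ift140 knockout, 1 for flow in the Dync2h1 knockout, 1 and 0 for the static and 1 and 1 for the under-flow genotype comparisons.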

How the results depend on the processing

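The planned count-based tests (edgeR as the main test, DESeq2 and voom as alternatives) were not run, since the files hold no counts. No list that passed and no named gene changed sign under the settings run for it. On the deposited TPM the median of all genes moved from 0.013 to -0.099 for the Dync2h1 knockout under flow and from 0.025 to -0.087 for the Dync2h1 difference. Counts of the flow and static comparisons stayed within 1.5 times of the values reported except where given here. Other pseudocounts, the fit without a mean-variance trend, library weights, protein-coding genes only, chromosomes left out, quantile normalisation and the fit of all comparisons without the library labelled Ift140 knockout flow replicate 3 were chosen after the data were seen. An alternative that gives no value for a result was not given for it. The cause was not tested unless stated.

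On the deposited TPM, the Ift140 difference in response fell to 19 genes and Ift140 under flow to -0.652 (adjusted p = 0.0801). With only the groups compared in the fit, counts were 604 for flow in the Ift140 knockout, 616 for the Ift140 knockout under flow, and 6 and 152 for the Ift140 and Dync2h1 differences, and Ift140 under flow, -0.673, had adjusted p = 0.205. On the deposited TPM the higher and lower counts were 1400 and 1338 for flow in wild type. Quantile normalisation gave 1714 and 1418 for the static Ift140 knockout and 17 higher and 60 lower genes for the mean difference. Protein-coding genes only gave 968 higher and 1485 lower for the static Ift140 knockout, 1421 and 2181 for the static Dync2h1 knockout, and 1852 and 2116 for the Dync2h1 knockout under flow, where all genes gave 2697 and 2334. Weights per library gave 78, 317 and 185 genes for the Ift140, Dync2h1 and mean differences. Without chromosomes 1, 5, 6 and 17, which leaves fewer genes, the Ift140 and mean differences held 23 and 45, the static Dync2h1 knockout 3068 (1829 higher, 1239 lower) and the Dync2h1 knockout under flow 2244 higher and 1263 lower.

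At an adjusted p under 0.01, which keeps fewer genes by construction, flow counts were 1986 (wild type), 1508 (Ift140 knockout) and 1734 (Dync2h1 knockout), differences 11, 35 and 34, static counts 1583 and 2921 and under-flow counts 1293 and 3183. At 2-fold they were 384, 339 and 346, then 14, 29 and 17, 451 (165 higher, 286 lower) and 837, and 390 and 878, with 311 of 634 named genes kept. Ift140 under flow, -0.673, passed neither threshold. With an estimated correlation 73 of 138 lists kept their call, with fry 126, on the deposited TPM 133, with median-ratio scaling 135 and with replicate numbers in the fit 135.

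The replicate block, which treats the replicate numbers as a factor, gave 22 genes for the Ift140 difference, and a block within genotype gave 6, 31 and 17 for the 3 differences. As a pairing check, deviations of static and flow libraries with the same number correlated between -0.04 and 0.1. No pairing by number was thus seen, which does not show how the cultures were run.

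Leaving out 1 library at a time, where a lone pair is assumed to vary like the other groups, gave 2493 to 4146 genes for flow in wild type, 2157 to 2997 in the Ift140 knockout and 2209 to 3991 in the Dync2h1 knockout. The differences ranged from 12 to 57 (Ift140), 42 to 160 (Dync2h1) and 41 to 140 (mean), static counts from 2063 to 3893 and 3555 to 5458, and under-flow counts from 1803 to 3072 and 3874 to 5858. The highest counts of the differences came without the library labelled Ift140 knockout flow replicate 3. Ift140 ranged from -1.384 to -1.271 in static culture and from -0.957 to -0.495 under flow, and Dync2h1 from -1.64 to -1.321 and from -1.78 to -1.532. The number of lists that passed ranged from 127 to 152. Depth is not known from TPM, so what it limits could not be measured.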

Other observations

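The chromosome test without the end of chromosome 6, the tests of chromosome 5 and the wider gene criterion for wild-type RNA were chosen only after the results were seen, and so were the genes of the next paragraph, after their values were seen.

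Beyond the genes named by rule, the following single genes, picked by hand, rose or fell at least 2-fold with flow in all 3 lines. The natriuretic peptide gene Nppb rose by 1.93 in wild type, 1.66 in the Ift140 knockout and 1.67 in the Dync2h1 knockout, and the neuropeptide precursor gene Vgf by 1.31, 1.52 and 1.84. Both stayed low in wild type, going from 0.368 to 4.2 TPM and from 0.447 to 2.6 TPM. The zinc exporter gene Slc30a1 rose by 1.75, 1.96 and 1.65, the heme transporter gene Slc48a1 by 1.24, 1.29 and 1.37, and the glutathione transferase gene Gsta1 by 2.99, 2.06 and 2.93. Transcription factor genes Runx1 (1.38, 1.53, 1.51), Cebpb (1.11, 1.26, 1.23) and Klf5 (1.35, 1.47, 1.03) rose too, as did the cytokine receptor gene Tnfrsf12a (1.60, 1.32, 1.33). Falls in all 3 lines were Lrp2bp (-1.87, -2.50, -2.69), the MYC antagonist gene Mxi1 (-1.26, -1.36, -1.29), the cell cycle inhibitor gene Cdkn2d (-1.48, -1.44, -1.28), the endothelin gene Edn1 (-1.17, -1.30, -1.28), Kif12 (-1.03, -1.34, -1.52) and the citrate transporter gene Slc13a2 (-1.31, -1.04, -1.32).

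The library labelled Ift140 knockout flow replicate 3 lay apart from its group. The SD of its log2 deviations was 0.379, its highest correlation with a library of its group 0.965, 16076 genes reached 1 TPM, and the nuclear RNAs Malat1 and Neat1 stood at 1002 and 75.4 TPM, against 444 and 36.5 and 446 and 36.7 in the other 2 libraries. Wild-type RNA under this label was tested with 10 genes nearly absent from the other 2 libraries, such as Serpinh1, Cubn and Grb10: the median share of the wild-type level was 0.0296% and the highest 3.8%, where Ift140 would need 85.1%, which speaks against it. Its deviations followed gene length (Spearman 0.428), but with length removed its SD was still 0.361 against at most 0.311 elsewhere, so length does not account for it. RNA quality and composition were not tested and stay open, and no biological explanation was tested.

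Coding genes of some chromosomes moved together, static and under flow: chromosome 17 in the Ift140 knockout by medians of 0.37 and 0.42 (481 genes), and in the Dync2h1 knockout chromosome 1 by -0.45 and -0.44 (541 genes), chromosome 6 by -0.45 and -0.43 (442 genes) and chromosome 5 by -0.25 and -0.23 (654 genes). Genes of other chromosomes matched for GC content, length and expression moved by at most 5.95% of the shift in its direction (5.36% for chromosome 5), and single libraries kept at least 86.7% of it (92% for chromosome 5), which speaks against gene properties and against a few libraries. A change of whole chromosomes does not account for chromosome 6, since its end (118501308 to 149563329) kept as little as 17.2%. The other parts, each holding 25% of the coding genes of its chromosome, kept at least 91.3%, and those of chromosome 5 at least 85.6%, so a copy number change of chromosomes 17, 1 and 5 and of most of chromosome 6 could account for the shifts. DNA was not measured here, and no biological explanation was tested.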
